A study of Escherichia coli with 16 samples.

How the data were processed

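RNA levels of Escherichia coli K-12 MG1655 were compared between a wild type strain and a strain carrying rpoH, the gene of the heat shock sigma factor sigma 32, under a promoter switched on by the inducer IPTG. Per the labels, both strains grew aerobically in minimal medium at 30 °C, received 1 mM IPTG at an OD450 of 0.3, and were sampled just before the inducer, called 0 min here, and then at 2.5 min, 5 min, 10 min and 20 min. Per the labels' protocols, total RNA was extracted with hot phenol, and 16 µg of it was primed with 10 µg of random hexamer and labelled indirectly. Each of the 16 arrays held wild type RNA in Cy3 and RNA of the RpoH strain in Cy5, taken at the same time, and no dyes were swapped. The arrays belong to 4 time courses, with n = 3 at 0, 2.5, 5 and 20 min and n = 4 at 10 min, since time course 4 holds the 10 min array alone.

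The authors deposited 1 log ratio per probe and array, and these deposited log2 ratios were the only measurements used. The base of the logarithm was not stated in the sources used here. A base of 10 was excluded by values reaching 6.43, and base 2 was taken by convention, so that a natural logarithm stays open and the folds given below rest on base 2. The direction, RpoH strain over wild type, is likely from the dye labels and from the positive ratio of rpoH on every array. The scanner, normalization, spot filter and genome build were not given in the sources used here. Array medians lay within 0.0408 of 0, so the deposited values behave as centred, and the lowest ratio was -3.43. Intensities were not analysed here, so that the signal over background of a spot is not known and the number of arrays sets the precision. A dye bias of a gene would enter every ratio with the same sign, and it would drop out of changes between times only where it was constant.

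Of 6400 probes, 3947 had a value on at least 1 array, and 3851 to 3930 had one on each array. The platform annotation gave 1 gene symbol to 3769 of the 3947, several to 0 and none to 178. All 3769 were matched by Entrez identifier in the RefSeq gene table of assembly ASM584v2, which changed 0 symbols, and no gene was measured by more than 1 probe. Tests covered the 3887 genes with a value on at least 2 arrays of every time point, of which 171 had no symbol and 3766 had a value on all arrays. No value column was left unmapped to a sample, with a count of 0.

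The ratios were used as deposited, with no further scaling. In limma 3.58.1 under R 4.3.3, 1 mean per time point was fitted to all 16 arrays, so that the groups shared 1 estimate of the spread with 11 residual degrees of freedom and a prior of 5.73. Moderated tests compared 2.5, 5, 10 and 20 min with 0 min, neighbouring times with each other, and the 0 min ratio with equal levels in both strains. All adjusted p values below are limma's with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Errors on changes are standard errors (SE) of that fit, and errors on ratios are standard deviations (SD) over arrays. Per the design text the time courses came from separate biological samples, which is the basis of the p values.

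There were 21 lists of genes, fixed before the data were examined: heat shock chaperones, heat shock proteases, other sigma 32 regulon members, the sigma E and Cpx envelope stress regulons, the lac operon, flagella and chemotaxis, ribosomal proteins, RNA polymerase core, sigma S general stress, amino acid biosynthesis, SOS response, cold shock, outer membrane porins and receptors, iron uptake, oxidative stress, TCA cycle, glycolysis, ATP synthase, aminoacyl tRNA synthetases and maltose uptake. All members were matched in the RefSeq gene table, but not all of them were among the genes tested. Tested were, for instance, 2 of 4 RNA polymerase core genes, 5 of 8 cold shock genes and 47 of 54 ribosomal protein genes. Counts below are out of the members tested. The list of other sigma 32 members was probably chosen in part from work on these arrays, so its direction is not independent evidence. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists. It ran in its pre-ranked form, since camera takes no missing values. Camera with a correlation estimated from the arrays, and fry, which asks whether a list's genes move one way on balance, ran on the 3766 complete genes.

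Genes were named by a rule fixed at the same time. It takes rpoH, the 10 highest and 10 lowest changes at 5, 10 and 20 min among genes past the threshold with the same sign in each time course, the 5 highest and 5 lowest by the same rule in the remaining comparisons, and up to 4 members with the smallest p from each list at each time. It named 195 genes, and each one called had the same sign of change in every time course. Genes named outside the rule are marked as chosen after their values were seen.

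Whether the time course number pairs the arrays was checked on deviations from the time point means over the 3766 complete genes. The 30 pairs from the same course correlated at 0.103 to 0.441, with a median of 0.259, and the 72 pairs from different courses at -0.41 to 0.18, with a median of -0.11. Where arrays of a course resemble each other, taking out the time point means pushes pairs from different courses below 0. Part of the gap between the medians is therefore built in. Each of the 15 arrays of courses 1 to 3 correlated best with an array of its own course. Every same-course pair lay above 0.1, so the number was taken as a pairing. The main fit leaves this pairing out, so its SE and p values treat the arrays of a time course as independent. Counts of genes from the fit with the time course as a block are given wherever they moved by over 1.5 times. Among the results on named genes that fit lost 0 calls and added 36, and only part of the added calls are given singly. No array ran against another over all genes, the lowest correlation of any 2 arrays being 0.0501.

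The fit was tested on simulated data built from the 3887 genes, with independent normal noise of each gene's own spread and no time course effect. Log2 changes of 0.5, 1 and 2 were planted together in 67, 67 and 66 genes, which eases the Benjamini-Hochberg threshold. With a log2 change of 1 added, 98.5% of the changed genes were recovered at 2.5 min, 95.5% at 5 min, 89.6% at 10 min and 94.0% at 20 min. At a log2 change of 0.5 the shares were 49.3%, 43.3%, 62.7% and 46.3%, and among 3687 genes left unchanged 10, 10, 5 and 11 were called. These shares hold for the simulated setting and need not hold for the arrays. In the data at 2.5 min a log2 change of -1.03 was not called. Alternatives were median centring, quantile and scale normalization between arrays, complete genes alone, no filter, the time course as a fixed or random block, the compared arrays alone, robust moderation, array weights, each ratio against equal levels, a 2-fold minimum, camera with an estimated correlation, fry, and each time course left out in turn.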

Results

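The study followed transcript levels in E. coli after a sudden supply of sigma 32, the sigma factor that directs RNA polymerase to heat shock promoters, at a constant 30 °C and so without a heat shock. Its purpose, per its title and design text, was to find genes regulated by sigma 32, and comparing both strains at the same time was meant to correct for changes in growth state. The data were log2 ratios of the RpoH strain over the wild type on 16 arrays, with 3887 genes tested.

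The transcript of rpoH (b3461) was already above the wild type before the inducer, at a log2 ratio of 1.74 ± 0.09 (SD, n = 3), a 3.34-fold difference. It reached 5.53 ± 0.40 (n = 3) at 2.5 min and then stayed at 5.51 ± 0.30 (n = 3) at 5 min, 5.68 ± 0.77 (n = 4) at 10 min and 5.63 ± 0.55 (n = 3) at 20 min. The 10 min mean corresponds to 51.3-fold over the wild type. The lowest value on any array was 1.65 and the highest 6.43.

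**Figure D1:**
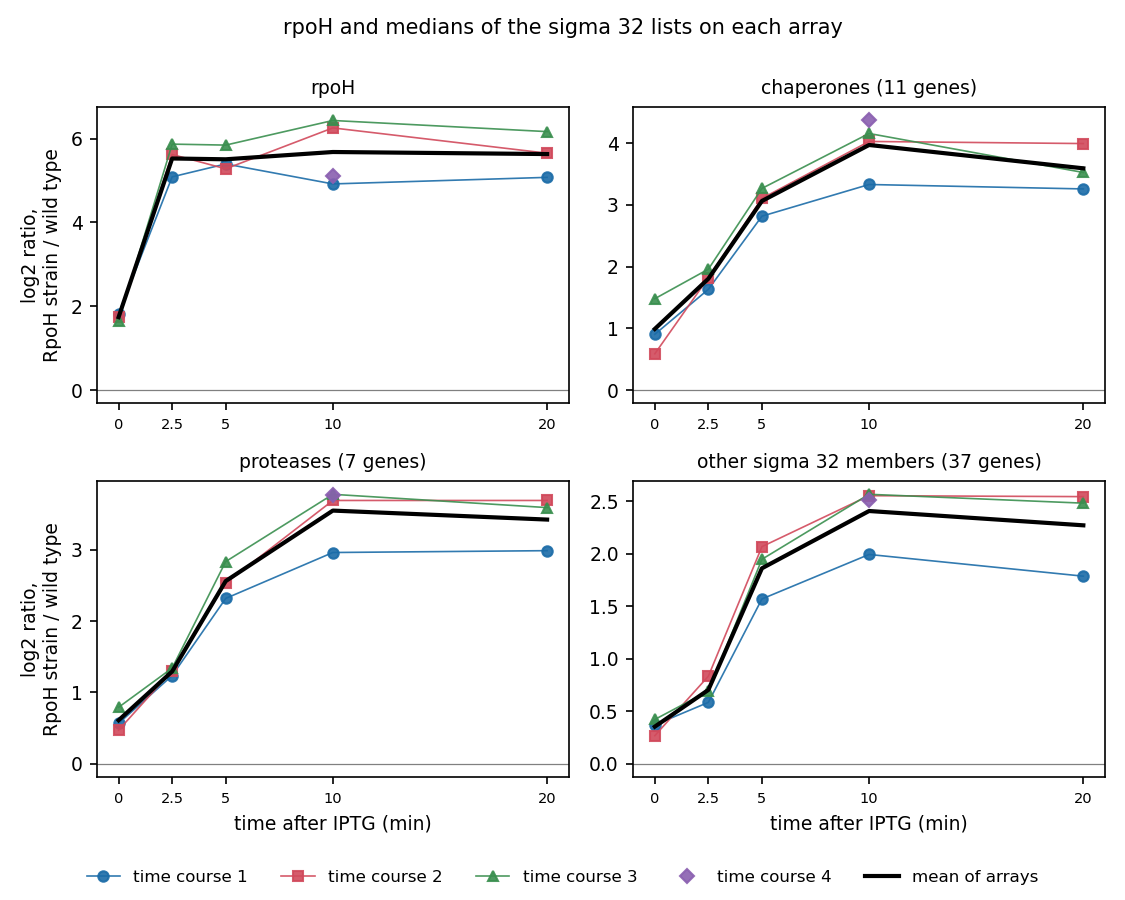
Log2 ratio of the RpoH strain over the wild type (vertical axis) against time after IPTG in min (horizontal axis), as rpoH itself and as the median of the 11 chaperone, 7 protease and 37 other sigma 32 genes on each array, with thin lines for time courses 1 to 3, a diamond for time course 4 and a thick line for the mean of the arrays. The mean of rpoH was 5.53 at 2.5 min, whereas the mean of the chaperone medians was 1.80 then and 3.97 at 10 min.

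Before induction the RpoH strain differed from the wild type in 355 of 3887 genes, of which 216 were higher and 139 lower. The small heat shock proteins ibpB (b3686) and ibpA (b3687), which bind aggregating proteins, were higher by 2.82 ± 0.23 (SE, n = 3) and 2.27 ± 0.13 on the log2 scale. Also higher were livJ (b3460), a binding protein for branched-chain amino acids, at 2.49 ± 0.19, and raiA (b2597), a ribosome-associated inhibitor, at 2.06 ± 0.27. The lowest were sbp (b3917), the periplasmic sulfate-binding protein, at -2.32 ± 0.36, the sulfite reductase gene cysJ (b2764) at -1.73 ± 0.28 and the flagellin gene fliC (b1923) at -1.68 ± 0.24. limma's adjusted p for these 7 genes ran from 1.6e-08 for ibpA to 0.00066 for cysJ. The sulfur genes cysI at -1.57 ± 0.37 and cysD at -1.53 ± 0.34 were also called lower, with adjusted p of 0.190 and 0.102 without time course 3 and 0.0586 and 0.0677 without time course 2, and 0.0529 for cysD without time course 1.

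Among the lists at 0 min, 8 of 11 chaperones were higher (11 adjusted over the list alone), with a median of 0.94. The proteases had 3 of 7 higher (5 adjusted over the list alone, median 0.59), and the other sigma 32 members had 9 of 37 higher and 1 lower (18 and 2 adjusted over the list alone, median 0.37). In the sigma S list, genes of the general stress response, 12 of 19 were higher (12 adjusted over the list alone), with a median of 0.61 and dps, a DNA-binding protein of starved cells, at 1.29. In the lac operon list 3 of 4 genes were higher (4 adjusted over the list alone), lacZ by 1.28 ± 0.24. The Cpx list had 2 of 10 higher (5 adjusted over the list alone), the sigma E list 5 of 24 (8) and amino acid biosynthesis 9 of 35 (10). Flagella and chemotaxis had 18 of 45 genes lower (23 adjusted over the list alone, median -0.27), and ribosomal proteins 17 of 47 (24, median -0.31). Aminoacyl tRNA synthetases were called lower as a list (median -0.12) with 0 of 22 genes called, over the list alone too. Of these 11 lists, those that kept their call with an estimated correlation were flagella (adjusted p = 0.0208), Cpx (0.0208), sigma S (0.0406) and lac (0.0406). The adjusted p with an estimated correlation was 0.0750 for chaperones, 0.208 for proteases, 0.265 for other sigma 32 members, 0.478 for sigma E, 0.205 for ribosomal proteins, 0.208 for amino acid biosynthesis and 0.330 for tRNA synthetases.

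The comparison at 0 min takes the ratio itself, with no dye swap to remove a dye bias of single genes. Leaving out time course 3 brought the 355 genes to 114, quantile normalization between arrays raised them to 590, and scale normalization to 598.

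**Figure D2:**
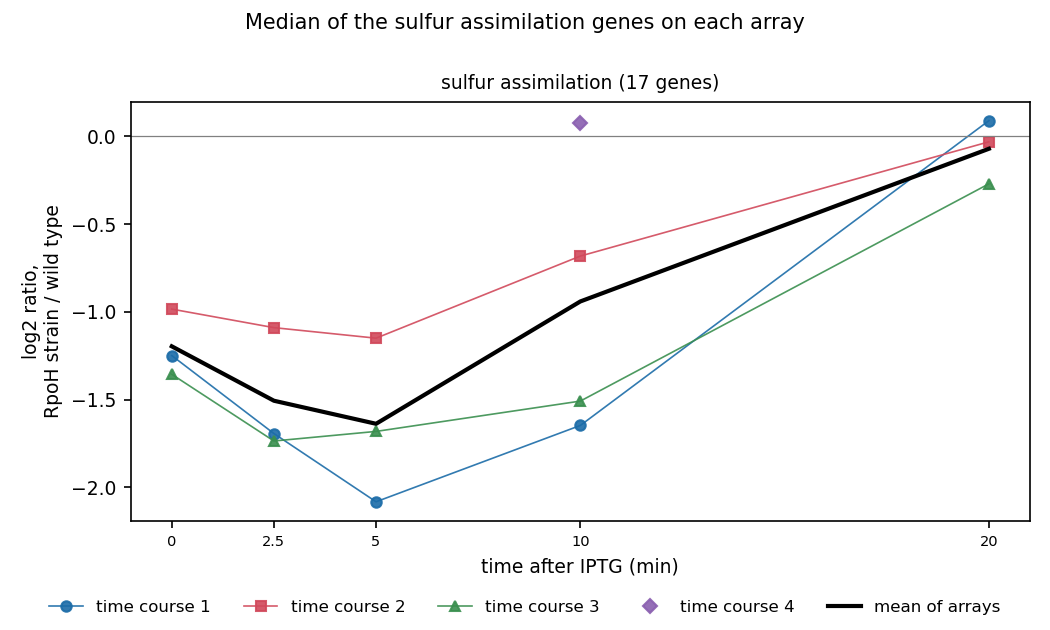
Median log2 ratio of the RpoH strain over the wild type (vertical axis) for 17 sulfur assimilation genes, a list chosen after the values were seen, on each array against time after IPTG in min (horizontal axis), with lines for time courses 1 to 3, a diamond for time course 4 and a thick line for the mean of the arrays. The medians lay between -1.36 and -0.98 at 0 min and between -0.27 and 0.09 at 20 min, and time course 4 was at 0.07 at 10 min.

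At 2.5 min the only gene past the threshold against 0 min was rpoH itself, which rose by 3.79 ± 0.35 (SE) on the log2 scale (adjusted p = 2.2e-05, higher in 3 of 3 time courses). With the time course as a block the count was 22, 14 higher and 8 lower, and 13 of the 22 were members of the 3 sigma 32 lists. In that blocked fit yhdN, a protein of unknown function beside zntR, rose by 1.27 ± 0.20, ybeD by 1.19 ± 0.14, the protease subunit hslV by 1.02 ± 0.12 and the DnaK nucleotide exchange factor grpE by 0.98 ± 0.13. The lowest were tomB at -1.03 ± 0.19 and hha at -0.87 ± 0.15, neighbouring genes for a biofilm modulator and a nucleoid-associated protein, with blocked adjusted p of 0.0219 and 0.0121. These blocked genes other than rpoH were chosen after their values were seen.

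Of the 11 chaperones 0 were called at 2.5 min over all genes, and 5 rose when adjusted over the list alone. The corresponding counts were 0 and 3 of 7 proteases and 0 and 12 of 37 other sigma 32 members. Their median changes were 0.76, 0.49 and 0.32, and each list shifted up against the other genes at the preset correlation (adjusted p at most 6.0e-06), but with an estimated correlation the adjusted p was 0.264 for all 3. Flagella (median 0.11, adjusted p = 0.0183), ribosomal proteins (0.10, 0.0183) and iron uptake (-0.18, 0.0048) were also called, with adjusted p of 0.788, 0.805 and 0.788 with an estimated correlation. With the time course as a block the sigma E list was called lower too (adjusted p = 0.0379, and 0.692 with an estimated correlation). In the same blocked fit the chaperones grpE, hslR and ibpA and the proteases hslV, clpP and htpX were called as risen over all genes. The lac list, not called, had a median of 0.05 and a mean of -0.04. Under quantile normalization 24 genes were higher and 17 lower, under scale normalization 3 and 5, without time course 1 the count was 3 and without time course 4 it was 2. Unadjusted, 207 genes had a p under 0.05.

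By 5 min 124 genes had changed, with 87 risen and 37 fallen, 123 of them with the same sign in every time course. After rpoH, the largest rises were zntR (b3292), a zinc-responsive regulator, by 3.01 ± 0.43 (SE), yhdN by 2.59 ± 0.28, hslV by 2.43 ± 0.20, and the chaperones dnaK (b0014) and clpB by 2.39 ± 0.38 and 2.39 ± 0.28, with limma's adjusted p between 1.1e-06 and 0.00072. The ribosome-associated RNA-binding heat shock protein hslR rose by 2.38 ± 0.27, the DNA glycosylase mutM by 2.31 ± 0.24 and the riboflavin synthesis gene ribE, which is in no list, by 2.30 ± 0.15. The largest falls were tomB (b0461) at -1.66 ± 0.19 and hha (b0460) at -1.56 ± 0.20. Among the other falls were gadW at -1.30 ± 0.30 and gadX at -0.90 ± 0.18, regulators of acid resistance, whose adjusted p became 0.275 and 0.139 without time course 3, and 0.105 for gadW without time course 2. The call on clpB was lost under quantile normalization (1.41, adjusted p = 0.0785).

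All 11 chaperones had risen at 5 min (11 adjusted over the list alone), with a median of 1.93, and all 7 proteases (7, median 2.00). Under quantile normalization 5 chaperones rose and ibpB, outside the naming rule here and singled out after its values were seen, was called as fallen. Of the other sigma 32 members, a list not independent of these arrays, 28 of 37 rose (33 and 1 fallen adjusted over the list alone), with a median of 1.60 and the tRNA modification gene miaA up by 1.78 ± 0.17. These 3 lists kept their call with an estimated correlation, at adjusted p of 0.0139, 0.0111 and 0.0111. In the sigma E list 2 of 24 genes fell (2 adjusted over the list alone, median -0.25), and in iron uptake 2 of 27 (5, median -0.31). Ribosomal proteins (1 of 47 risen, 1 adjusted over the list alone, median 0.23) and flagella (1 of 45, 1, median 0.13) shifted up, and sigma S genes (0 of 19 called, 0 over the list alone, median -0.22) shifted down. These 5 calls were lost with an estimated correlation, with an adjusted p of 0.526 for sigma S and 0.477 for the other 4. The tRNA synthetase genes ileS, valS and glnS rose by 1.03 ± 0.14, 1.15 ± 0.22 and 1.13 ± 0.25, while their list of 22 was not called (adjusted p = 0.701). Without time course 3 the adjusted p was 0.205 for valS and 0.196 for glnS, and without time course 2 it was 0.142 for glnS. Of the lac operon lacZ alone was called, at 1.42 ± 0.33 (3 genes adjusted over the list alone, and 1 fallen), a call lost under quantile normalization (0.05) and without time course 2 (adjusted p = 0.328).

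The blocked fit called 203 genes at 5 min, 114 higher and 89 lower, among them all 124. The share of rises, 70.2%, fell to 49.4% under quantile normalization (124 higher, 127 lower) and to 50.6% under scale normalization (127 higher, 124 lower). Quantile normalization gives every array the same set of ratios, which removes rises on balance, so its share cannot judge the excess of rises. Scale normalization gives every array the same spread, whereas the SD over genes of the deposited ratios was 0.290 to 0.344 at 0 min and 0.401 to 0.455 at 5 min. The count of 124 became 63 without time course 2 and 52 without time course 3.

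At 10 min 656 genes had changed, 287 up and 369 down, 646 of them with the same sign in every time course. For time course 4, which has no 0 min array, the sign was taken against the mean of the 0 min arrays. Beside rpoH at 3.94 ± 0.33, the disulfide-regulated chaperone hslO rose by 3.55 ± 0.29, hslR by 3.53 ± 0.25, the lactate dehydrogenase gene ldhA by 3.46 ± 0.21, and rpoD (b3067), the gene of the housekeeping sigma factor, by 3.45 ± 0.35, with limma's adjusted p of at most 2.0e-06. The ratio of rpoD was 3.39 ± 0.70 (SD, n = 4) and lower in time course 1, at 2.35, than on the other 10 min arrays, at 3.70 to 3.81. The lowest changes were tomB at -2.33 ± 0.18, hha at -1.93 ± 0.19, gadW at -1.77 ± 0.28, hdeA, a periplasmic acid stress chaperone, at -1.59 ± 0.25, and yciI at -1.50 ± 0.22.

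The median rise was 3.07 over the 11 chaperones and 2.90 over the 7 proteases, and all 18 of these genes rose (18 adjusted over the lists alone). Among them dnaJ rose by 3.08 ± 0.22, lon by 2.87 ± 0.22 and clpP by 2.97 ± 0.25. Under quantile normalization 8 chaperones rose and ibpA and ibpB, chosen after their values were seen, were called as fallen, against 1.47 ± 0.17 and 1.36 ± 0.30 with the deposited ratios. Of the other sigma 32 members 35 of 37 rose and 1 fell (35 and 1 adjusted over the list alone), with a median of 2.06. The exceptions, named after their values were seen, were metA, of methionine synthesis, which fell by 0.43 ± 0.09, and rfaD at 0.05 ± 0.12. The adjusted p of the 3 lists with an estimated correlation was 0.0382, 0.0365 and 0.0343. In time course 1 the protease median was 2.96 and the other sigma 32 median 1.99, below the other 10 min arrays at 3.69 to 3.78 and 2.52 to 2.57.

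In the lac operon lacZ (b0344) rose by 2.69 ± 0.31, lacA by 2.59 ± 0.29 and lacY by 2.02 ± 0.33 (3 of 4 genes, 3 and 1 fallen adjusted over the list alone). These calls ended under quantile normalization, at 0.47, 0.86 and 0.93, and the list's adjusted p was 0.0049 at the preset and 0.10 with an estimated correlation. In the sigma E list 10 of 24 genes fell (12 adjusted over the list alone, median -0.38), such as rseA, the anti-sigma factor of sigma E, at -1.28 ± 0.15 and bamD at -0.67 ± 0.10. In the sigma S list 8 of 19 fell (10, median -0.48), such as dps at -1.19 ± 0.22 and osmE at -1.18 ± 0.21. In the iron uptake list 9 of 27 fell (14, median -0.44), in amino acid biosynthesis 8 of 35 (9, median -0.28), such as ilvB at -0.96 ± 0.13, and in oxidative stress 3 of 16 (4, median -0.26). The Cpx list had 5 of 10 genes fallen and 1 risen (5 and 1 adjusted over the list alone, median -0.39). Ribosomal proteins had 10 of 47 risen (13, median 0.31), such as rpsL at 1.07 ± 0.18, and flagella 6 of 45 (5, median 0.23), or 13 under quantile normalization. With an estimated correlation the adjusted p was 0.121 for sigma E, 0.170 for sigma S, 0.240 for iron uptake and oxidative stress, 0.121 for amino acid biosynthesis, 0.0800 for Cpx, 0.326 for ribosomal proteins and 0.259 for flagella, so that none of these 8 calls was kept.

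With the time course as a block 937 genes were called at 10 min, 634 of them among the 656, and the Cpx call was lost (adjusted p = 0.0577). Leaving out time courses 1, 2 and 3 gave 400, 342 and 211 genes. Without time course 3 the excess of falls turned over, to 124 risen and 87 fallen genes, and other groupings of the same arrays called as many as 14 lists, against 12.

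**Figure D3:**
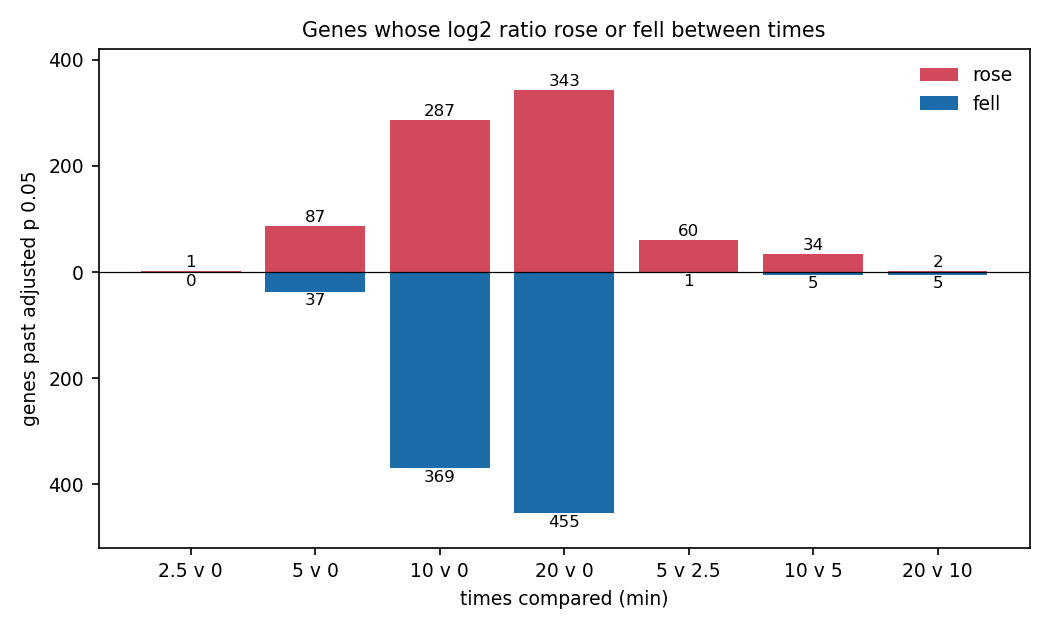
Number of genes past an adjusted p of 0.05 (vertical axis) whose log2 ratio rose (bars above 0) or fell (bars below 0) in each comparison of times in min (horizontal axis). Against 0 min the bars grow from 1 gene at 2.5 min to 343 risen and 455 fallen genes at 20 min, and between 10 and 20 min they hold 2 and 5 genes.

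By 20 min 798 genes had changed, 343 up and 455 down, 792 of them with the same sign in every time course. The largest rise was that of sdaC (b2796), a serine transporter, by 3.91 ± 0.23, from a log2 ratio of -0.76 ± 0.22 (SD, n = 3) to 3.15 ± 0.44 (n = 3). Next to rpoH at 3.89 ± 0.35 came ribE (b0415) at 3.74 ± 0.15, hslO and hslR at 3.33 ± 0.31 and 3.33 ± 0.27, ldhA at 3.31 ± 0.22, zntR at 3.28 ± 0.43 and hslJ, the chromosomal neighbour of ldhA, at 3.18 ± 0.32. The lowest changes were raiA at -2.57 ± 0.38, hdeA at -2.44 ± 0.27, gadW at -2.17 ± 0.30, dps at -2.11 ± 0.24 and tomB at -2.09 ± 0.19, with limma's adjusted p of at most 0.000102. The galactitol transport gene gatA was at -2.01 ± 0.50 and lost its call without time course 3 (-1.25, adjusted p = 0.186).

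At 20 min 10 of 11 chaperones (10 adjusted over the list alone), all 7 proteases (7) and 34 of 37 other sigma 32 members (34) were called as risen from 0 min, with median changes of 2.84, 2.78 and 1.89. The chaperone not called was ibpB at 0.40 ± 0.32, and metA was the 1 list member that fell, at -0.53 ± 0.10, both chosen after their values were seen. Under quantile normalization ibpA and ibpB were called as fallen. With an estimated correlation the adjusted p was 0.0593 for chaperones, 0.0507 for proteases and 0.0507 for the other members, and 0.0365 for each with the time course as a block.

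General stress genes of the sigma S list had fallen in 13 of 19 cases (14 adjusted over the list alone, median -0.85), with elaB at -1.41 ± 0.18, osmE at -1.81 ± 0.23 and osmY at -1.84 ± 0.24. Ribosomal protein genes had risen in 30 of 47 cases (36 adjusted over the list alone, median 0.56), with rpsL at 1.24 ± 0.19, rpsG at 1.18 ± 0.14 and rplF at 0.83 ± 0.13. In the sigma E list 14 of 24 fell (17, median -0.53), with the periplasmic protease degP at -1.75 ± 0.28, rseA at -1.61 ± 0.16 and bamD at -0.95 ± 0.11. In the oxidative stress list 8 of 16 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.36), with the peroxidase gene ahpC at -1.06 ± 0.21. The adjusted p with an estimated correlation was 0.0593 for sigma S, sigma E and oxidative stress and 0.137 for ribosomal proteins. In the blocked fit it was 0.0365 for sigma S, ribosomal proteins and oxidative stress and 0.0437 for sigma E.

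In the Cpx list 6 of 10 genes fell and 1 rose (6 and 1 adjusted over the list alone, median -0.56), with yccA at -1.70 ± 0.31, yebE at -0.85 ± 0.16 and the chaperone gene ppiD up by 0.92 ± 0.20. Amino acid biosynthesis had 12 of 35 fallen (17, median -0.46), with metE, the final enzyme of methionine synthesis, at -1.12 ± 0.18 and argG at -0.50 ± 0.11. Iron uptake had 8 of 27 fallen (11, median -0.46), with the receptor gene fhuE at -1.38 ± 0.24. The lac list had 3 of 4 risen and 1 fallen (3 and 1 adjusted over the list alone), with lacZ up by 2.95 ± 0.33, lacA by 2.44 ± 0.31 and lacY by 2.11 ± 0.35, calls that ended under quantile normalization at 0.86, 0.76 and 0.94. The fallen gene was the repressor lacI at -1.04 ± 0.35, whose adjusted p of 0.0463 became 0.111, 0.250 and 0.0513 without time courses 2, 3 and 4. Flagella had 8 of 45 risen (7, median 0.27), with fliK up by 0.77 ± 0.14. With an estimated correlation the adjusted p was 0.0507 for Cpx, 0.0593 for amino acid biosynthesis, 0.210 for iron uptake, 0.0835 for lac and 0.161 for flagella.

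In glycolysis 3 of 8 genes fell and 1 rose (7 and 1 adjusted over the list alone, median -0.49), with tpiA at -0.86 ± 0.15 and gapA, also a sigma 32 member, up by 0.94 ± 0.19. In the TCA cycle 5 of 13 fell (6, median -0.47), with sucD at -0.93 ± 0.22, and in ATP synthase 1 of 7 (2, median -0.27). Of the porins and receptors 4 of 12 fell (4, median -0.25), with ompT at -1.44 ± 0.22. Cold shock genes rose in 2 of 5 cases (2, median 0.37), cspA by 1.17 ± 0.24 and deaD by 1.00 ± 0.19. These 5 lists had adjusted p of 0.0105, 0.0488, 0.0414, 0.0432 and 0.0491 at the preset and 0.150, 0.273, 0.294, 0.261 and 0.294 with an estimated correlation, and quantile and scale normalization ended the TCA, ATP synthase and porin calls. Not called were the SOS response (2 of 17 risen, 2 adjusted over the list alone, recA by 0.96 ± 0.17), aminoacyl tRNA synthetases (3 risen and 2 fallen of 22, 3 and 5 adjusted over the list alone), maltose uptake (2 risen and 1 fallen of 7, 2 and 2) and the RNA polymerase core (1 of 2 risen, 1). The tRNA synthetase median was -0.14 and its mean 0.08, and the maltose median was -0.09 with a test direction of up. Among the synthetases glnS rose by 2.10 ± 0.25, valS by 2.03 ± 0.22 and ileS by 1.81 ± 0.14.

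With the time course as a block 1039 genes were called at 20 min, 797 of them among the 798. Leaving out time course 2 gave 484 genes and leaving out time course 3 gave 305, where the excess of falls turned into 159 risen and 146 fallen genes, and other groupings of the same arrays called as many as 15 lists, against 17.

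**Figure D4:**
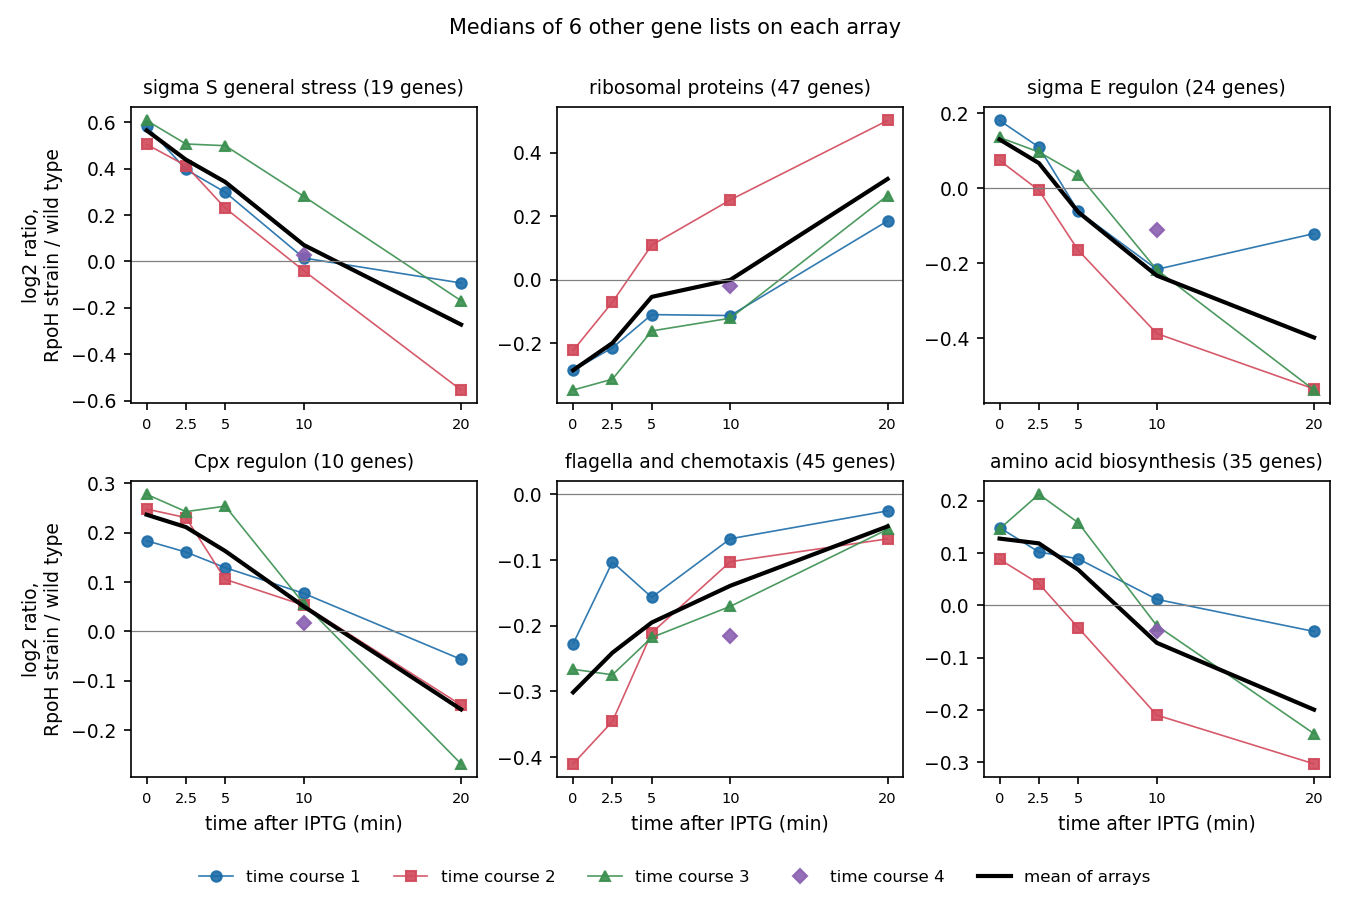
Median log2 ratio of the RpoH strain over the wild type (vertical axes) on each array for 6 gene lists against time after IPTG in min (horizontal axes), with lines for time courses 1 to 3, a diamond for time course 4 and a thick line for the mean of the arrays. The mean of the array medians of sigma S genes went from 0.57 at 0 min to -0.27 at 20 min and that of ribosomal protein genes from -0.29 to 0.32.

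Neighbouring times show when ratios still moved. Between 2.5 and 5 min 60 genes rose and 1 fell, with ribE up by 1.99 ± 0.15, mutM by 1.88 ± 0.24 and ydhQ by 1.80 ± 0.23 (limma's adjusted p at most 0.00029). The fallen gene was fnr, the regulator of anaerobic growth, at -0.45 ± 0.10, with an adjusted p of 0.0758 in the compared arrays alone and of at least 0.289 with any of time courses 1 to 3 left out. The rpoH ratio itself did not pass the test over this interval, at -0.02 ± 0.35. Between 5 and 10 min 34 genes rose and 5 fell, with sdaC up by 2.06 ± 0.21, the isoprenoid synthesis gene ispH by 1.65 ± 0.20 and sdaB, a serine deaminase beside sdaC, by 1.65 ± 0.25. The gene hdeA was at -1.24 ± 0.25, with an adjusted p of 0.207 without time course 3 and 0.0597 without time course 4. Between 10 and 20 min 2 genes rose and 5 fell, among them the succinyl-CoA synthetase gene sucC and metE, both at -1.03, with SE of 0.20 and 0.16. Both calls were lost in the compared arrays alone, under quantile and scale normalization, and without time course 2 or 3.

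With the time course as a block the 3 counts were 93 (86 up, 7 down), 160 (102 up, 58 down) and 68 (29 up, 39 down). Under quantile normalization they were 66 (48 up, 18 down), 22 (13 up, 9 down) and 1, under scale normalization 78, 21 (12 up, 9 down) and 0, and they fell to 23, 17 and 0 without time course 2 and to 13, 15 and 1 without time course 3. The 7 genes between 10 and 20 min became 1 without time course 1 and 11 without time course 4.

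All 87 genes that had risen at 5 min and all 37 that had fallen were also called the same way at 10 min. Independent lists of these sizes would share 6.42 and 3.51 genes. At 20 min 85 of the 87 and 30 of the 37 were called, against 7.68 and 4.33 for independent lists. From 10 to 20 min 232 rises and 269 falls were shared, against 25.3 and 43.2. All of these comparisons use the same 3 arrays at 0 min, too few to split, so part of the excess may come from the shared 0 min arrays.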

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

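Every test in this part other than the regrouping of arrays was chosen only after the result was seen.

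At 10 min, the only time with 4 arrays, Dixon's test was applied to each gene, and 209 of 3857 genes, or 5.42%, had an array apart from the other 3, close to the 1 in 20 set by its 95% level. Among the 195 named genes there were 17. Time course 1 was apart for rpoD at 2.35 (others 3.70 to 3.81), the protease subunit clpX at 2.00 (3.77 to 3.79), ibpB at 3.48 (4.37 to 4.45), lacI at -0.67 (0.34 to 0.47), the chemotaxis gene cheY at -0.56 and the DNA repair gene uvrA at -0.64. Its medians of the proteases, 2.96, and of the other sigma 32 members, 1.99, were also apart. Time course 2 was apart for sdaC at 3.00 (2.11 to 2.26), osmE at -0.71, the aconitase gene acnB at -0.76, argG at -0.20, umuC at 0.52 and flgB at -0.10. Time course 3 was apart for raiA at 1.68 (0.43 to 0.64), rpoS, the gene of sigma S, at 0.28 (-0.46 to -0.35), and the ribonuclease gene pnp at -0.68. Time course 4 was apart for the prolyl isomerase gene ppiA at -0.58 and the helicase gene dinG at 0.29. By time course the 209 genes divide into 56, 73, 41 and 39.

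Of the 216 genes called above the wild type at 0 min 64 were called below it at 20 min, and of the 139 called below 11 were called above. Their change from 0 to 20 min was called as well. Among the named genes, the acid and general stress genes hdeA (-2.44), gadW (-2.17), dps (-2.11), yeaQ (-1.86), osmY (-1.84), osmE (-1.81), sra (-1.68), elaB (-1.41) and rpoS (-1.08) changed across equal levels in this way. So did the envelope genes degP (-1.75), yccA (-1.70), rseA (-1.61), bamD (-0.95) and dolP (-0.76), as well as tomB (-2.09), hha (-1.62), the ribonucleotide reductase gene nrdF (-1.56), yciI (-1.53), fhuE (-1.38), artJ (-1.25) and ahpC (-1.06). In the other direction went sdaC (3.91) and the ribosomal protein genes rpsL (1.24), rpsG (1.18), rplF (0.83), rplO (0.83) and rplB (0.68).

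In the sigma S list 8 of 19 members turned from called above the wild type to called below it, and the list's median change was -0.85, with -0.47, -1.17 and -0.70 in time courses 1, 2 and 3. A constant dye bias would cancel in this change, so the value of -0.85 argues against it as the source of the fall. It cannot tell where equal levels lie, since no dyes were swapped. Whether the genes truly crossed the wild type level therefore stays open. The median change of all genes was 0.0296, but the deposited values behave as centred, which fixes this value near 0, so a shift of the arrays' centre stays open. The ribosomal protein list lay below the wild type at 0 min and rose in 3 of 3 time courses, by 0.48, 0.69 and 0.57, though with an estimated correlation its adjusted p was 0.205 at 0 min and 0.137 for the change to 20 min (0.0365 with the time course as a block). This rise goes with a hypothesis in which the strains differ in growth state at 0 min and the difference turns, but other lists were mixed. From 0 to 20 min the median ratio went from -0.12 to -0.32 for tRNA synthetases and from -0.14 to -0.40 for ATP synthase. It went from -0.27 to -0.03 for flagella and from -0.04 to 0.17 for the RNA polymerase core. Growth rates were not analysed here, so the hypothesis stays open.

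Regrouping the arrays asks how often another division gives as many calls. For 2.5, 5 and 20 min against 0 min and for 5 against 2.5 min, 1 of 10 divisions, the real one, gave as many genes, the highest other count being 0, and 10 divisions are too few for a share below 0.05. For 10 against 0 min it was 1 of 35, with 656 genes in the real division and 371 in the highest other. Of the 8 divisions that part all pairs of a time course, only the real one gave as many (highest other 212), and 8 are too few for a share below 0.05. For 10 against 5 min 2 of 35 gave as many, the highest other count being 61 (7 among the 8 that part all pairs), and for 20 against 10 min 4 of 35, the highest other being 166 (8 among those parting all pairs). The division with 166 sets time course 1 at both times and time course 4 against time courses 2 and 3, which points to a structure by time course, and the blocked counts were 160 and 68. Chance was not excluded for these 39 and 7 genes. For lists the shares were 3 of 10 at 2.5 min, 3 of 10 at 5 min, 7 of 35 at 10 min and 1 of 10 at 20 min, with up to 9, 8, 14 and 15 lists in other divisions.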

How the results depend on the processing

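Counts of genes moved by over 1.5 times under several alternatives. Quantile normalization gave 41 genes at 2.5 min and 251 at 5 min against 0 min, 22 for 10 against 5 min, 1 for 20 against 10 min and 590 at 0 min. Scale normalization gave 8, 251, 21, 0 and 598 for the same 5. The time course as a block gave 22 at 2.5 min, 203 at 5 min, 93 for 5 against 2.5 min, 160 for 10 against 5 min and 68 for 20 against 10 min, and as a random block 13 at 2.5 min, 100 for 10 against 5 min and 18 for 20 against 10 min. The compared arrays alone gave 5 at 2.5 min, 24 for 10 against 5 min and 0 for 20 against 10 min. Array weights gave 16 at 2.5 min, 202 at 5 min, 87 for 10 against 5 min and 543 at 0 min. Ratios against equal levels gave 264, 419 and 1235 genes at 2.5, 5 and 10 min, and a 2-fold minimum 72, 140 and 212 at 5, 10 and 20 min, 22 for 10 against 5 min, 2 for 20 against 10 min and 52 at 0 min. Camera with an estimated correlation called 0 lists at 2.5 min, 3 at 5 min, 3 at 10 min and 0 at 20 min, and fry 0 at 2.5 min and 3 at 5 min. At 10 and 20 min fry called 14 and 17 lists, against 12 and 17 at the preset correlation. With 1 time course left out the counts against 0 min ranged from 1 to 3 at 2.5 min, 52 to 126 at 5 min, 211 to 648 at 10 min and 305 to 805 at 20 min. They ranged from 13 to 60 for 5 against 2.5 min, 15 to 55 for 10 against 5 min, 0 to 11 for 20 against 10 min and 114 to 361 at 0 min, and for lists from 3 to 6 at 2.5 min, 7 to 10 at 5 min, 11 to 15 at 10 min and 13 to 17 at 20 min. Called changes that turned included those of the chaperone genes ibpB at 5 min and ibpA and ibpB at 10 min. They had risen with the deposited ratios and were called as fallen under quantile normalization, as was ibpA at 20 min. Quantile normalization gives every array the same set of ratios, so a gene's value there follows its rank among the genes. Both genes ranked among the highest at 0 min, so they fall there when other genes pass them, even where their own ratio rises. The rpoH changes of 0 given below also follow from its rank. Among the genes named by the rule, signs turned for changes not called. At 2.5 min lacZ went from 0.07 to -0.25 under quantile normalization and atpA from 0.08 to -0.0138 with array weights. The rpoH changes after 2.5 min became 0 under quantile normalization in all 3 intervals, -1.36 under scale normalization for 10 against 5 min, and 0.0547 and 0.0397 with array weights for 5 against 2.5 and 20 against 10 min. With 1 time course left out rpoH ranged from -0.18 to 0.14 for 5 against 2.5 min, -0.13 to 0.37 for 10 against 5 min and -0.24 to 0.13 for 20 against 10 min. At 2.5 min the ranges were -0.17 to 0.21 for atpA, -0.27 to 0.0769 for atpB, -0.19 to 0.40 for lacA, -0.0585 to 0.13 for lacY, -0.0044 to 0.11 for lacZ, -0.0189 to 0.28 for lysS, -0.49 to 0.0625 for malM, -0.35 to 0.0173 for ompF, -0.16 to 0.0313 for pgk and -0.0861 to 0.11 for rbfA. At 5 min they were -0.16 to 0.0260 for cspI, -0.0238 to 0.29 for malF and -0.33 to 0.0099 for mdh, and at 20 min -0.0127 to 0.20 for cspI.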

Other observations

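The tests and gene groups in this part were all chosen only after the result was seen. Of 3 genes of serine uptake and breakdown, 2 rose at 5 min, 3 at 10 min and 2 at 20 min against 0 min. The transporter gene sdaC and the deaminase gene sdaB rose by 3.16 ± 0.21 (SE) and 2.29 ± 0.25 at 10 min, and sdaA, of another deaminase, by 1.51 ± 0.23, with limma's adjusted p of at most 0.000238. At 20 min sdaA was no longer called (0.46, adjusted p = 0.213). The glycine cleavage genes gcvT, gcvH and gcvP, which break down glycine, fell by 1.13, 1.11 and 0.98 at 20 min.

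The 4 genes of the manganese-dependent ribonucleotide reductase fell at 20 min, nrdI by 1.62 ± 0.32 and nrdH by 1.10 ± 0.27, with a median of -1.46 over the group. Galactitol uptake fell in 4 of 6 genes (median -1.28), and of 9 O-antigen and sugar genes 0 were called at 20 min (median -0.53, limma). The ratio of livJ, beside rpoH on the chromosome, decreased from 2.49 at 0 min to 1.52 at 10 min. Of 17 sulfur assimilation genes 16 were called as below the wild type at 0 min (median -1.16), 17 at 5 min (-1.58), 14 at 10 min (-0.86) and 0 at 20 min (-0.09).

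At 10 min the sulfur median was -1.65, -0.68 and -1.51 in time courses 1, 2 and 3 and 0.07 in time course 4. An array holding a 20 min sample could give this, and on a scale from the mean 10 min to the mean 20 min profile that array lay at 0.417, among the other 10 min arrays (0.184, 0.270 and 0.585) and below all 20 min arrays (0.494, 0.642 and 0.914). Its ribosomal protein median of -0.02 lay among the other 10 min arrays (-0.12 to 0.25) and below those at 20 min (0.19 to 0.50), whereas its ribonucleotide reductase median of 0.02 lay above both (-1.16 to -0.55 and -1.40 to -0.31). Of these values only the position and the ribosomal median lean against a 20 min sample. The positions of both times overlap, with 0.585 for time course 2 at 10 min and 0.494 for time course 1 at 20 min. The distance of 0.417 from the nearest 20 min array is also smaller than the spread of the 10 min arrays, so the question stays open. A pull of all ratios towards 0 is argued against by the slope of 1.14 ± 0.05 for the time course 4 array over the sigma 32 lists, against 0.793, 0.957 and 1.02 on the other 10 min arrays.

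The lac genes and araB, an arabinose gene up by 2.43 ± 0.22 at 10 min, might rise through the inducer itself. Of their 10 min change at most 0.0732 had been reached at 2.5 min, against 0.961 for rpoH, so their ratios did not move at its pace. Both strains received IPTG, and a response shared by both cancels in the ratio. The pace therefore cannot test a direct effect of the inducer. At 5 min the share was 0.528 for lacZ and 0.489 for araB, near the 0.578 to 1.19 of 18 chaperone and protease genes, which decides nothing. The shares of lacY at 0.458 and lacA at 0.288 lay further below that range. These genes share an operon with lacZ, so their shares are no separate test and the pace of the operon stays undecided. The genotype behind these genes was not given in the sources used here.

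Risen genes outside the sigma 32 lists lay next to a listed gene more often than other genes, 17 of 223 (7.62%) against 45 of 3437 (1.31%; one-sided Fisher's exact p = 7.6e-08). Examples are hslJ (2.88), menA (1.90), ybeX (1.81) and cspD (1.62). Transcription running on from a sigma 32 promoter may be 1 hypothesis for them. The test counted neighbours on either side of a listed gene and did not use the strand, so its p cannot judge that hypothesis. It also used the list of other sigma 32 members, which is not independent of these arrays. Transcript ends were not analysed here.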
